A study of Homo sapiens and Mus musculus with 10 samples.

How the data were processed

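The series measured the binding of proteins and histone modifications to DNA with ChIP-DIP in 10 samples. Per the labels' protocols, fixation took 10 minutes in 1% formaldehyde, chromatin was sonicated, and protein-bound chromatin was captured with a mixed pool of Protein G beads that carried antibodies and antibody-specific oligonucleotides. DNA ends were repaired and tailed, split-and-pool barcodes were added, and the DNA was amplified for 8 to 12 cycles. Per the submitters' processing notes, Trim Galore 0.6.2, FastQC 0.11.9, cutadapt 2.5, Bowtie2 2.3.5, SAMtools, bedtools 2.29.0, MultiQC 1.6 and deepTools 3.4.3 were used, with the genome builds mm10 and hg38. No output of those steps was used here.

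The data analysed are the antibody lists deposited by the authors, 1 for each of 7 pools, with 5 columns per the file headers: entry number, product name, antibody target, supplier and catalogue number. They hold text and no measurement, count or signal. Sequencing depth and the precision it would give are therefore unknown here. Shares of reads per antibody with exact binomial intervals, and rank agreement of counts between pools, had been planned for lists that held counts and were not run. The 4 samples titled 45M, 5M, 500K and 50K share the K562 35 list, so that these amounts could not be compared, and neither could the 3 times of lipopolysaccharide stimulation. Each pool was otherwise 1 sample, the numbers in the labels pair no samples, and no replicate spread could be computed. No statistical test was made between lists.

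Lists were read with Python 3.11.15 and drawn with matplotlib 3.10.9. Written target names were trimmed and folded for case, spaces and hyphens. A second set of names, called unified here, joined synonyms and notations. Histone notations were rewritten by rule (for example as H3K27ac), and 94 written names were assigned by hand from the name itself or the product name of the same entry, after the tables had been seen. All 134 gene symbols used in unified names were looked up in a table of human genes and were found there. Mouse targets were matched to it by name. Phosphorylated forms of a protein were kept apart from the protein, and antibodies against lamins A, B1 and C together were kept as 1 target. Isoforms written under 1 gene symbol were joined. Folding and the count of shared names were run on simulated lists with known overlaps, and the true values were returned. Those names differed only in case, hyphens and spaces, which folding removes, so that recovery was assured. Synonyms, the suppliers' notations and the names assigned by hand were not simulated. The rewriting of histone notations was checked on a few chosen notations with known results, which it returned.

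Entries per pool were counted line by line. Targets were assigned to the first of 16 classes that they matched, each target counting once per pool under its unified name. Shared targets were counted for the 21 pairs of lists, controls left out, with folded written names as planned and with unified names beside them. Classes, comparisons and most alternatives were fixed before the data were examined. The use of unified names, the class counts with written names set against them, the count without empty beads and the removal of a trailing letter from Cell Signaling catalogue numbers were added afterwards. A count was taken as kept when it stayed within 1.5 times the reported one.

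Targets were named by a rule fixed before the data were examined: every control type, every target with 2 or more antibodies in a pool up to 10 per pool, every target common to the lists of a cell type or to all lists, and up to 4 targets of each class and pool in alphabetical order. Some targets that this rule gives are not named here. Any other target is named with the statement that it was chosen after the tables were seen, or as the whole of a group of 5 or fewer.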

Results

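ChIP-DIP is a multiplexed form of chromatin immunoprecipitation. Each antibody is coupled to beads that carry an identifying oligonucleotide, the beads are pooled into 1 immunoprecipitation, and split-and-pool barcoding then links each DNA molecule to the antibody on its bead. The series applied the method to 10 samples, and each of its 7 bead pools had its own list of antibodies. The samples came from K562 cells, a human leukaemia line, from PSM44 mouse embryonic stem cells (mESC), and from mouse primary dendritic cells (mDC), which take up antigen and respond to bacterial products. K562 cells were used with 4 lists, whose titles give 10, 52, 50 and 35 antibodies. The 35-antibody list served 4 samples, titled 45M, 5M, 500K and 50K. The mESC samples had lists of 165 and 67 antibodies, and the single mDC sample had a list of 25. Per the labels, dendritic cells were stimulated with 100 ng/ml of lipopolysaccharide, a component of the bacterial outer membrane, for 0, 6 or 24 hours. The values analysed here are the contents of the 7 lists, which hold no read counts, so that sequencing depth is unknown and binding of the targets to DNA was not analysed here. Each list is a complete count of a pool chosen by the experimenters. It has no sampling error, and no test was made between lists. There were no replicates.

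The first comparison asked how many antibodies and targets were placed in a single pool. The mESC 165 list was the longest, with 163 antibody entries against 119 distinct proteins or protein forms, from the pluripotency factor NANOG to the Polycomb methyltransferase EZH2. They are mostly chromatin proteins and transcription factors, but an entry written Polycystin-2 was read by name alone as PKD2, a membrane channel, and stays among the 119. It is named here after the tables were seen. The K562 10 list was the shortest, with 7 antibodies against 7 targets, which included the insulator protein CTCF and the promoter mark H3K4me3. Between them stood the mESC 67 list with 64 antibodies against 47 targets, the K562 52 list with 48 against 38, the K562 50 list with 45 against 39, the K562 35 list with 33 against 29, and the mDC 25 list with 24 against 24. These counts leave out control beads and join synonyms of a target, as well as isoforms written under 1 gene symbol. Counted line by line with controls, the 7 lists held 11, 54, 52, 36, 166, 68 and 26 entries for the pools titled 10, 52, 50, 35, 165, 67 and 25. Over the 7 lists there were 413 entries, 384 of them antibodies against chromatin or other cellular targets, and these named 188 distinct targets. Leaving out controls took the K562 10 list from 11 entries to 7, because 36.4% of its entries were controls.

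Beads without antibody and rabbit IgG, which measure background capture, were present in all 7 lists. Human IgG1 Fc was present in 6, and the mDC 25 list was the exception. Goat anti-mouse IgG was present in the K562 52 and K562 50 lists. The remaining control types stood in 1 list each. The K562 10 list had an antibody against the V5 tag, the K562 52 list had biotinylated anti-rabbit IgG, and the K562 50 list had antibodies against GFP and fluorescein. Beads without antibody were entered 2 times in the K562 52 list and 2 times in the K562 50 list, and rabbit IgG was entered 2 times in the mESC 67 list. The share of control entries was 36.4% in K562 10, 13.5% in K562 50, 11.1% in K562 52, 8.33% in K562 35, 7.69% in mDC 25, 5.88% in mESC 67 and 1.81% in mESC 165.

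The second comparison asked which parts of chromatin each pool addressed, using 16 classes fixed before the data were examined, with controls and a residual class among them. A class holds only the targets that its list of names, fixed beforehand, picks out, and related proteins outside that list fell in the residual class. Histone modifications and chromatin proteins were divided unevenly between the pools. Modified histones made up 22 of the 24 targets of the mDC 25 list (91.7%) and 38 of the 47 targets of the mESC 67 list (80.9%). They made up 15 of 39 targets in K562 50 (38.5%), 11 of 29 in K562 35 (37.9%) and 2 of 7 in K562 10 (28.6%). The K562 52 and mESC 165 lists had 0 targets of this kind among 38 and 119. With the target names as written, before the suppliers' notations were joined, the class patterns recognised 0 modified histones in K562 50, 0 in K562 35 and 16 in mESC 67.

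**Figure D1:**
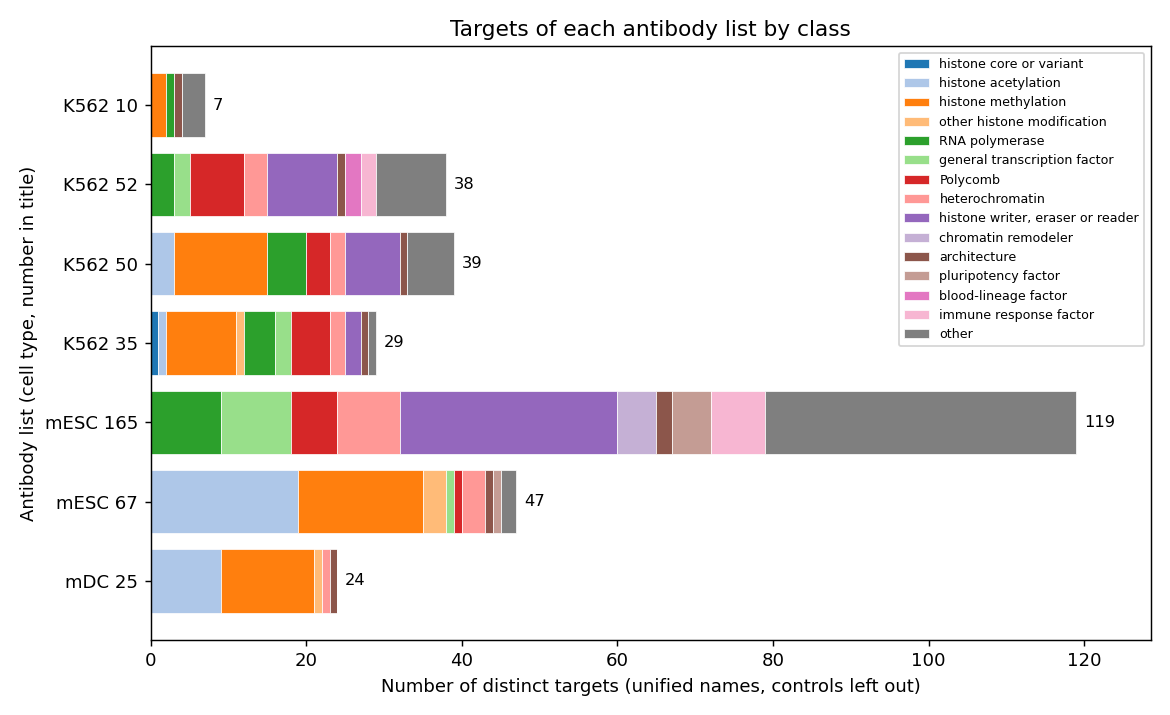
Horizontal bars give the number of distinct targets (x axis, unified names, controls left out) in each of the 7 antibody lists (y axis, cell type and number in the title), with 1 colour per class and the total at the end of each bar. Modified histones fill 22 of 24 targets in mDC 25 and 38 of 47 in mESC 67, and none of the 119 in mESC 165.

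Histone methylation was represented by 16 targets in mESC 67, 12 in mDC 25, 12 in K562 50, 9 in K562 35 and 2 in K562 10. The mESC 67 set opened alphabetically with H3K27me2, the Polycomb mark H3K27me3, H3K36me3 of transcribed gene bodies and the enhancer mark H3K4me1. The mDC 25 set opened with the same 4 marks. In K562 50 the first were H3K27me3, H3K36me2, H3K36me3 and H3K4me1, in K562 35 they were H3K27me3, H3K36me3, H3K4me1 and H3K4me2, and K562 10 held H3K27me3 and H3K4me3. The account by residue in the next sentences was chosen after the tables were seen. At H3K4 the 3 methylation states were covered in K562 50, K562 35, mESC 67 and mDC 25, whereas K562 10 covered trimethylation alone. At H3K9, whose trimethylation marks heterochromatin, the mESC 67 and mDC 25 lists covered 3 states, and the K562 50 and K562 35 lists covered 1. At H3K27 the mESC 67 and mDC 25 lists covered 2 states and the K562 10, K562 50 and K562 35 lists covered 1. At H3K36 the K562 50 list covered 2 states, and the K562 35, mESC 67 and mDC 25 lists covered 1. At H3K79 there were 3 states in K562 50 and mESC 67 and 2 in K562 35 and mDC 25. Methylated arginines were listed in mESC 67 alone, as H3R17me2a, H3R8me2a and H4R3me2s.

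Histone acetylation, a modification of active chromatin, was represented by 19 targets in mESC 67, 9 in mDC 25, 3 in K562 50 and 1 in K562 35. The mESC 67 set opened with H2A.ZK4K7ac, H2BK12ac, H2BK15ac and H2BK20ac, and the mDC 25 set with H2BK12ac, H2BK15ac, the enhancer and promoter mark H3K27ac, and H3K36ac. K562 50 held H3K27ac, H3K4ac and H3K9ac, and K562 35 held H3K27ac. By histone, the mESC 67 list had 9 acetylation targets on H3, 4 on H2B, 4 at single residues of H4 and 1 on the variant H2A.Z. Among those on H2B, H2BK5ac, named after the tables were seen, was read as acetylated from its product name. The mDC 25 list had 4 on H3, 2 on H2B and 3 on H4. Other histone modifications numbered 3 in mESC 67, namely H2AK119ub, which Polycomb complexes deposit, H2BK120ub, which accompanies transcription, and the mitotic mark H3S10ph. H2AK119ub was also in K562 35 and H3S10ph in mDC 25. Histone H3 with no stated modification was listed in K562 35.

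RNA polymerases were represented by 9 targets in mESC 165, 5 in K562 50, 4 in K562 35, 3 in K562 52 and 1 in K562 10, and by 0 in mESC 67 and mDC 25. The mESC 165 set opened with POLR1A of RNA polymerase I, POLR3D and POLR3E of RNA polymerase III, and RNA Pol II without a stated phosphorylation. K562 50 held POLR3A, and K562 52, K562 50 and K562 35 each held RNA Pol II and its carboxy-terminal domain phosphorylated at serine 2 (S2ph) and at serine 5 (S5ph), forms of elongating and early transcribing polymerase. The form S2/S5ph was in K562 50, K562 35 and mESC 165. Forms phosphorylated at serine 7 (S7ph) and threonine 4 (T4ph), named after the tables were seen, were in mESC 165 alone. The class of general initiation and elongation factors had 9 targets in mESC 165, CDK8, ELL and GTF2F1 among them. K562 52 and K562 35 had 2 each, and both held the TATA-binding protein TBP. CCNT1, the cyclin of the elongation factor P-TEFb, was the 1 in mESC 67.

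Polycomb repressive complexes were covered by 7 targets in K562 52, 6 in mESC 165, 5 in K562 35, 3 in K562 50 and 1 in mESC 67. The K562 52 set included CBX8, EED and EZH2. In mESC 165 the first 4 were AEBP2, EZH2, JARID2 and PHC1, and in K562 35 they were CBX8, EED, EZH2 and RNF2. K562 50 held EED, EZH2 and SUZ12, the core of Polycomb repressive complex 2, and mESC 67 held EED. Heterochromatin proteins numbered 8 in mESC 165, opening with the H3K9me3 reader CBX5, the DNA methyltransferases DNMT3A and DNMT3B, and the H3K9 methyltransferase EHMT2. There were 3 in K562 52 (CBX1, CBX5 and SUV39H1) and 3 in mESC 67 (CBX1, the lamin B receptor LBR, and an antibody against lamins A, B1 and C). K562 50 had 2 (the same lamin antibody, and an entry written Lamin-B that was read as LBR from its product name), K562 35 had 2 (CBX1 and LBR), and mDC 25 had CBX1.

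The class of other enzymes and readers of histone modifications was the largest class of proteins apart from the residual one in 3 lists, with 28 matched targets in mESC 165, 9 in K562 52 and 7 in K562 50, and K562 35 held 2. Those of mESC 165 opened with ASH2L, BRD3, CREBBP and HCFC1, those of K562 52 with the acetyltransferases CREBBP and EP300 and the deacetylases HDAC1 and HDAC2, and those of K562 50 with EP300, HAT1, HDAC2 and KDM1A. K562 35 held the methyltransferases SETD1A of H3K4 and SETD2 of H3K36. TET1 and TET2, named after the tables were seen, were matched by name among the 28 of mESC 165. They act on DNA bases and not on histones. The class of ATP-dependent remodelling complexes had targets in mESC 165 alone, 5 by the first class matched, which opened with MBD3, MTA1 and MTA2 of the NuRD complex and the catalytic subunit SMARCA4 of the SWI/SNF complex. HDAC1 and HDAC2, also subunits of NuRD, were counted with the histone-modifying enzymes. Of architectural proteins, CTCF was in K562 10, K562 50, K562 35, mESC 67 and mDC 25. YY1 was in K562 52, and YY1 and the cohesin subunit RAD21 were in mESC 165.

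The class of embryonic stem cell factors had 5 targets in mESC 165, opening with E2F1, which is also a general cell-cycle factor, KLF5, NANOG and POU5F1. In mESC 67 it had SOX2, and in the K562 and mDC lists it had 0. The class of blood-lineage factors had 2 targets, BACH1 and the erythroid regulator GATA1, both in K562 52, while other factors that act in blood cells fell in the residual class, among them BACH2 in K562 52, ERG in K562 50, named after the tables were seen, and BCL6 and CBFB in mESC 165. The class of immune response factors had 7 targets in mESC 165, opening with EGR1, FOS, FOS phosphorylated at serine 32 and HIF1A. Phosphorylated forms of FOS and JUN counted apart from the proteins among these 7. In K562 52 it had 2, FOS and JUN. The class name comes from the list of names fixed beforehand, and no immune role of these targets was tested. The mDC 25 list had 0 in this class, and beside modified histones it held CTCF and CBX1 alone. The residual class held 40 targets in mESC 165, 9 in K562 52, 6 in K562 50, 3 in K562 10, 2 in mESC 67 and 1 in K562 35. It included ATF2, BCL6, CBFB and CLOCK in mESC 165, BACH2, CTBP2 and beta-catenin (CTNNB1) in its non-phosphorylated form in K562 52, and actin, CTNNB1 and EIF3B in K562 50. SP1, TCF7L2 and ZFX made up that of K562 10, the DNA bases 5-hydroxymethylcytosine and 5-methylcytosine that of mESC 67, and SP1 that of K562 35.

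Several targets had more than 1 entry in the same pool. In mESC 165, 32 targets had 2 or more entries, 76 in all, and for KDM4A and KDM5A, named after the tables were seen, the 2 entries were 1 product entered 2 times. POU5F1 had 5, the most of any target in a list, and EZH2, HDAC2, NANOG, NONO, PHF8, RNF2, SIN3A, SP1 and YY1 had 3 each. In mESC 67, 13 targets had 30 entries. H3K9ac had 4, H3K4me2 and H4K20me3 had 3 each, and CTCF, H2BK120ub, H3K18ac, H3K27me3, H3K36me3, H3K4me3 and H3K79me2 had 2 each. K562 52 had 10 such targets, each with 2 antibodies, and EED, EP300, FOS, HDAC2, RNA Pol II, SETD1A, SETD2, SUZ12 and TBP were among them. The 6 of K562 50 were CTCF, H3K27ac, H3K27me3, H3K4me1, H3K4me2 and RNA Pol II S2ph, and the 4 of K562 35 were CTCF and RNA Pol II, RNA Pol II S2ph and RNA Pol II S5ph, again with 2 each. K562 10 and mDC 25 had 0.

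The third comparison asked how far the pools could be set against each other target by target. No target was in all 7 lists. RNA Pol II was the 1 target common to the 4 K562 lists, and SOX2 was the 1 target common to both mESC lists, out of the 165 unified targets that either held. Lamin A, named after the tables were seen, was also addressed in both mESC lists. Its antibody in mESC 67 is against lamins A, B1 and C together and counted as a separate target. Of the 188 targets, 126 were in 1 list, 31 in 2, 13 in 3, 14 in 4 and 4 in 5. Those 4, chosen after the tables were seen, were CTCF, H3K27me3, H3K4me3 and RNA Pol II. For each, 1 antibody product was in the same 5 lists as the target.

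Within K562, the K562 50 and K562 35 lists shared 18 written target names, 31% of the 58 that either held, and 19 of 49 targets under unified names (38.8%). K562 52 and K562 35 shared 15 written names and 14 unified targets, among them CBX8, EED and TBP. K562 52 and K562 50 shared 6 written names and 9 unified targets, but 2 antibody products. K562 10 shared 3 written names with K562 52, 2 with K562 50 and 3 with K562 35, and under unified names 3, 4 and 5. Of the 29 targets of the K562 35 list, 27 were also in another K562 list. The other 2 were H2AK119ub and histone H3 with no stated modification.

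Between cell types, the pair with the most shared names was K562 52 and mESC 165, with 22 written names and 25 unified targets, including CBX5, CREBBP, EZH2 and YY1. These 25 were 18.9% of the 132 unified targets that either held. By this share mESC 67 with mDC 25 stood highest, at 51.1%. By antibody product K562 52 and mESC 165 shared 7, or 13 without the trailing letter of the catalogue number, and mESC 67 and mDC 25 shared 15, or 24. K562 50 and mESC 67 shared 14 written names and 17 unified targets. K562 35 and mESC 67 shared 14 and 15, and K562 35 and mESC 165 shared 12 and 12. The overlap of mDC 25 with mESC 67 was 11 written names, 15.3% of 72, and 24 unified targets, 51.1% of 47, which is the whole mDC 25 list. It moved from 1 to 12 for mDC 25 and K562 50, and from 1 to 11 for mDC 25 and K562 35. The mESC 165 and mDC 25 lists shared 0 under written and unified names.

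**Figure D2:**
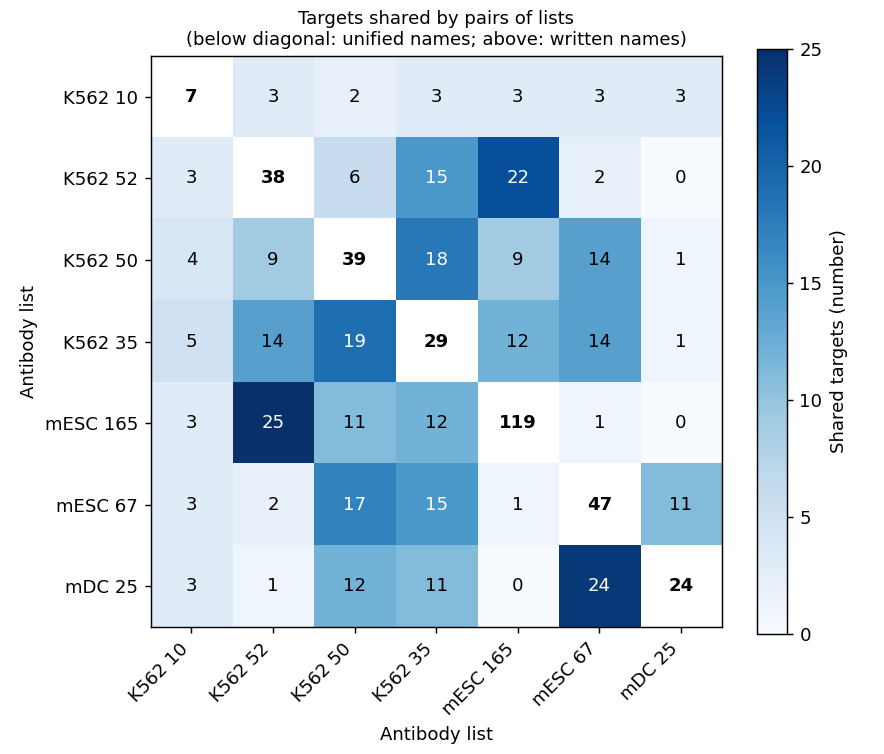
The matrix gives the number of targets shared by each pair of antibody lists, with unified names below the diagonal and folded written names above it, and the number of unified targets of each list on the diagonal in bold. Darker blue stands for more shared targets, and the mDC 25 and mESC 67 pair has 24 under unified names and 11 under written names.

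Grouped by cell type with unified names, the K562 lists named 71 targets, the mESC lists 165 and the mDC list 24. K562 and mESC had 48 in common, of which 14 were histone modifications and 34 were other targets. K562 and mDC had 13 in common, and these 13 were also in the mESC lists. With written names the count common to K562 and mDC was 3. In no other cell type's list were 23 of the K562 targets, 106 of the mESC targets and 0 of the mDC targets. Of the modified histones, 24 were in the mESC lists and in no K562 list, and 2 were in a K562 list and in no mESC list, H3K36me2 and H3K79 methylation as seen by an antibody against its mono-, di- and trimethylated forms together. Each of these H3K79 forms had an antibody of its own in mESC 67. Of Polycomb proteins, EED, EZH2, JARID2, RNF2 and SUZ12 were listed for both cell types.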

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

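Settings fixed beforehand for read shares per antibody and for rank agreement between pools were not run, since the lists hold no counts. The alternatives with unified names, written names for classes (exact or folded), no empty beads and no pack letter were chosen after the tables were seen. With 1 exception, entries per pool stayed within 1.5 times under each alternative; leaving out control lines took K562 10 from 11 to 7. Counting every antibody or every class matched kept the counts of modified histones and of other targets within 1.5 times in all 7 lists. With written names for classes, by exact or folded spelling alike, modified histones went from 15 to 0 in K562 50, from 11 to 0 in K562 35 and from 38 to 16 in mESC 67, and other targets from 24 to 44, from 18 to 32 and from 9 to 43 in the same lists. Exact spelling alone also took other targets of mDC 25 from 2 to 4, since H2BK12Ac and H2BK15Ac, with a capital A, missed the class patterns. Longer forms such as Acetyl-Histone H3 (Lys9) missed them under both. Of 56 single class counts, 22 moved under exact written names, 21 under folded ones, 10 when every antibody was counted and 0 when every class matched was counted. For shared targets, exact spelling kept 21 of 21 pairs within 1.5 times, and older symbols joined through the gene table left 21 of 21 equal. Keeping controls raised K562 10 with K562 52 from 3 to 5, with K562 50 from 2 to 5, with K562 35 from 3 to 5, with mESC 165 from 3 to 6 and with mESC 67 from 3 to 6; K562 52 with mESC 67 from 2 to 4 and with mDC 25 from 0 to 1; mDC 25 with K562 50 and with K562 35 from 1 to 2, and with mESC 165 from 0 to 1; and the mESC lists from 1 to 4. Unified names moved K562 10 with K562 50 from 2 to 4 and with K562 35 from 3 to 5, K562 52 with mDC 25 from 0 to 1, and mDC 25 with K562 50 from 1 to 12, with K562 35 from 1 to 11 and with mESC 67 from 11 to 24. Supplier and catalogue number gave 4 for K562 10 with K562 50 and 5 with K562 35, 2 for K562 52 with K562 50 against 6, 7 for K562 52 with mESC 165 against 22, 0 for K562 52 with mESC 67 against 2, 4 for K562 50 with mESC 165 against 9, 12 for K562 50 and 9 for K562 35 with mDC 25 against 1, and 0 for the mESC lists against 1. Without the pack letter the values were 4, 5, 2, 13, 4, 12 and 11 for the same pairs in that order, K562 52 with mESC 67 being within 1.5 times, then 0 for the mESC lists, 1 for K562 52 with mDC 25 and 24 for mESC 67 with mDC 25. Products count an antibody and names count a target. Apart from the notation of names, treated under the other observations, the cause was not tested.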

Other observations

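All tests in this part were chosen after the tables were seen.

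The mDC 25 list was contained in the mESC 67 list product by product. Each of its 24 target antibodies matched an antibody of the mESC 67 list in supplier and, leaving out a trailing letter, in catalogue number. By this matching its 22 modified histones, CTCF and CBX1 were each listed with the same reagent in both lists. With the letter kept, 15 products were shared. Over all 7 lists, 284 antibody products were directed against targets and 55 of them were in 2 or more lists: 28 in 2, 15 in 3, 8 in 4 and 4 in 5. Cell Signaling products made up 208 of the entries with an antibody, Bethyl products 82, of which 77 were in mESC 165, Active Motif products 64 and Abcam products 39, of which 27 were in K562 50. Antibodies against KDM4A and KDM5A, a pair of histone demethylases, were each entered 2 times under 1 catalogue number in mESC 165. Across lists, 17 products were entered under catalogue numbers that differed in 1 trailing letter alone. Since products were counted without that letter, this describes the matching and is no test of it.

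In 3 entries of mESC 165 the antibody target is a calendar date. A candidate explanation is spreadsheet conversion of the name Oct-4, the older name of the pluripotency factor POU5F1. In 3 of 3 such entries the product name holds Oct-4 and the date falls on the fourth day of October. These entries count under POU5F1 here. No biological explanation was tested.

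The numbers in the sample titles lie below the number of entries in 7 of 7 pools. The hypothesis that the titles leave out beads with no antibody was tested by removing those beads, 9 in all, and the remaining number equalled the title in 7 of 7 pools.

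In 8 of the 21 pairs of lists, fewer written names than antibody products were shared, catalogue numbers being compared without the pack letter. The hypothesis was notation of the target names, that is, 1 product written with different names in the 2 lists. In 4 of the 4 such pairs with mDC 25, the shared products written differently were at least as many as the missing names. This outcome was fixed in advance and is no test, since the 24 antibodies of mDC 25 have 24 distinct written names. In K562 50 with mDC 25, 11 names were missing and 11 of the 12 shared products were written differently. Of the 4 such pairs of other lists, K562 10 with K562 50 and with K562 35 were likewise fixed. The 7 antibodies of K562 10 have 7 distinct written names. By count, the relation held in 3 of these 4 pairs. The exception was K562 35 with mESC 67, where 2 names were missing and 1 of the 16 shared products was written differently, so that notation was not the whole cause there. The product written differently was that against LBR. The other missing name came from CTCF, whose 2 shared products were both written CTCF and so gave 1 name. In K562 50 with mESC 67, the pair that held and was not fixed, 2 names were missing. There 2 of the 16 shared products were written differently. Its 2 shared CTCF products likewise gave 1 name, which was offset by EED, a name shared through different products. Notation was thus not the whole cause in that pair either.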
